A study of Drosophila melanogaster with 3 samples.

How the data were processed

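The samples were 3 biological replicates of chromatin immunoprecipitation followed by sequencing (ChIP-seq) from whole Drosophila melanogaster embryos of both sexes, collected at 0 to 24 h of age. The flies carried a transgene for Hybrid male rescue (Hmr) with green fluorescent protein (GFP) at its C terminus, and an antibody against GFP pulled down the tagged protein with the DNA bound to it. Per the labels, the chromatin was sonicated and the fragments spanned 200 to 800 bp. The replicate numbers came from the labels. There was 1 group, so no contrast between conditions was possible, and no group shared replicate numbers with another.

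The authors deposited peak lists, not read counts, so the sequencing depth of each replicate is unknown and no value here could be scaled by it. Each list was in narrowPeak form. Per the text files deposited with the samples, a relaxed list of peaks and background had been called for each replicate against a control, another relaxed list for the 3 replicates pooled, and an optimal list had been kept from these by the irreproducible discovery rate (IDR), which asks whether a peak ranks alike in replicates. The peak caller, its version, the aligner and the IDR threshold are not given in the sources used here. Every list came in 2 genome builds, dm6 and dm3. Values are from dm6 unless dm3 is named.

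The authors' signal value of each peak was used only within 1 list, to rank peaks and to compare medians between classes of peaks, since its scale moves with depth. The deposited column 9 holds −log10 of the caller's q-value by the definition of the format. It was tied at its highest value for 5216 of the 8131 optimal peaks in dm6, so it was not used to rank peaks. Column 10 of the deposited lists gives the distance from the start of a peak to its summit, and summits were taken from it. Each relaxed list held exactly 30000 entries, so the number of entries says nothing about a replicate. The 8131 optimal peaks were exactly the 8131 pooled entries of highest signal, and in dm3 the same held for 7522 peaks. The dm6 lists covered only chromosomes 2L, 2R, 3L, 3R, X and 4. Coordinates are given from 1, in dm6.

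Gene models and the soft-masked sequence were of Release 6 of the fly genome, the assembly of dm6, with FlyBase gene identifiers. They held 18164 genes apart from transposable elements on the 6 chromosomes, of which 13945 were protein-coding. Of the symbols in the gene lists, 2 were not found (calypso and rye) and 2 were found through synonyms (hiphop and h).

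An optimal summit was called matched in a replicate when a summit lay within 200 bp among the 8131 strongest entries of that replicate's list. Chance was set by 1000 random circular shifts of the summits within each chromosome, but the optimal peaks come from the pooled reads of the same replicates, so this p-value is not printed. Spearman correlations were taken over peaks matched in both full lists, and their permutation p-values are left out because the peaks were chosen by the pooled signal of the same replicates. Background regions were the 20064 entries of the pooled relaxed list with no optimal summit within 500 bp. These regions passed through the same library, control and mapping as the peaks and are themselves weak candidates for binding. A promoter summit lay within 250 bp of an annotated transcription start, and a distal one farther than 1000 bp. The centromere-proximal set was the 2 Mb of each arm nearest the centromere plus chromosome 4. Shares were compared by Fisher's exact test, two-sided, and intervals of shares are exact Clopper-Pearson 95% intervals, which cover counting error only. Differences of medians and means were tested by two-sided permutation with 100000 resamples, or 10000 for the median signal of promoter peaks with and without each sequence. P-values below 1e-300 are given as 1e-300.

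Fixed before the data were examined were 22 gene lists, 16 consensus sequences, the tests, the rule for named genes and most alternatives. A gene counted as having a summit when 1 lay within 250 bp of any of its starts. Each list was compared with all other protein-coding genes, or with all other genes for the histone, tRNA and snRNA lists, with Benjamini-Hochberg adjustment over the 22 lists. Head-to-head genes were protein-coding genes with the start of another on the opposite strand within 500 bp upstream. Consensus matches on either strand were counted within 100 bp of each summit and in windows of the same width centred 500 bp to each side. The exact McNemar test was made against the flank of lower coordinate, whatever the strand of the gene, with Benjamini-Hochberg adjustment over 16 sequences. The rule named the genes nearest to the 15 strongest summits with head-to-head partners, up to 3 genes per list with the strongest peaks at their starts, and Hmr and Lhr.

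Summits, genes and peaks are not independent replicates, so p-values across them measure only whether a pattern exceeds chance in this set of peaks. No control without the GFP tag was analysed here. Near-identical gene copies, such as histone, tRNA, snRNA and Hsp70 genes, are uncertain, because reads from them may not have been placed. To follow this, 32-mers that occur once in the assembly were mapped, and a start was called mostly unique when at least 80% of the 32-mers within 250 bp of it were unique. The read length is not given in the sources used here.

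Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data. Of 22 lists, 1 planted list was found with 0 others, and of 16 sequences, 1 planted sequence was found with 0 others besides the shorter core it contains. With nothing planted, 0 lists and 0 sequences were called higher, that core again left out of the count, and 0 of 6 chromosomes departed from chance. The sequences were simulated at random positions, where windows and flanks differ in base composition only by chance. False calls from the base composition of real summits therefore could not show. The alternatives tried were other match distances, start windows and window widths, the stronger peaks, peaks matched in all 3 replicates, other backgrounds, the dm3 lists and setting aside each replicate in turn. Without a replicate means that only optimal peaks matched in the top lists of both other replicates were kept. For agreement and rank correlation that replicate was instead left out of the mean. The peaks still came from the pooled reads of all 3 replicates. These settings therefore keep fewer of the same peaks and do not test independence from a replicate.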

Results

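Chromatin bound by GFP-tagged Hmr was profiled in 3 biological replicates of whole fly embryos aged 0 to 24 h. Hmr is a DNA-binding protein known from hybrid incompatibility between fly species and from its association with Lhr and the heterochromatin protein HP1. The deposited lists allow 3 questions, namely whether the replicates found the same sites, where these sites lie in the genome, and which genes and sequences lie at them. The optimal list held 8131 peaks with a median width of 456 bp and a median signal of 276, from 154 to 6656. Depth is unknown, and signal is the authors' value for each peak.

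The 15 strongest sites lay at a mixed set of genes. The strongest peak of all lay on chromosome 2L from 480555 to 481387, in an intron of ush, which encodes a GATA cofactor, and 1382 bp upstream of cbt, which encodes a zinc-finger protein. Its signal was 6656, and it ranked 1 in each of the 3 replicates. The next peak lay on 2L from 6612390 to 6612995 in an intron of CG11050, with a signal of 6191 and rank 2 in each replicate. The peak at Ugalt, the gene of a UDP-galactose transporter, lay on X from 2703660 to 2704106, with its summit 42 bp upstream of the start, and ranked 3 in each replicate. Of the genes of other chromatin proteins, Trl, which encodes GAGA factor, carried an intronic peak 1529 bp inside the gene on 3L from 14759269 to 14759829 with a signal of 4831. Chro, which encodes the interband protein Chromator, carried a peak 81 bp inside its start on 3L from 22878676 to 22879132, 186 bp upstream of its head-to-head neighbour Ssl1, with a signal of 3514. A peak within introns of both HmgZ and HmgD, genes of HMG-box chromatin proteins, lay on 2R from 21703019 to 21703718 with a signal of 3600. CG14100, Tina-1, PNPase, mRpL41 and CenG1A had summits within 250 bp of a start, with signals from 3399 to 4872. The head-to-head partner of CenG1A, mRpS23, had its start 388 bp from the summit. The remaining strong peaks lay in introns of Lk6, CG32772 and CG9663, and in an exon of lncRNA:Vinr nearest to the start of lncRNA:CR44619, with signals from 3483 to 4628. All 15 were matched in the top lists of all 3 replicates.

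Neither Hmr nor its partner gene Lhr stood among the strong sites. No optimal summit lay at the start of Hmr on X, where the nearest was 4832 bp away in an intron of CG1628. Lhr on 2R had a summit 54 bp upstream of its start, in a peak from 17430750 to 17431205, but the start of Bap55 was nearer at 15 bp. This peak ranked 7243 with a signal of 170, and it was matched in the top list of 1 replicate.

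Most optimal sites had an entry in every replicate list, and the weaker ones ranked lower there. Of the optimal summits, 80.5% were matched among the strongest entries of replicate 1, 81.2% in replicate 2 and 84.4% in replicate 3, a mean of 82.0% ± 2.05 (SD, n = 3). All 3 replicates matched 4857 summits (59.7%), whose median signal was 386. Exactly 2 replicates matched 2219 summits (27.3%), 1 replicate matched 1000 and none matched 55. Among the strongest decile of the peaks, 99.1% were matched in all 3 replicates, against 3.32% of the weakest decile. This slope follows at least in part from the match rule, which asks for a place among the strongest entries of each replicate, so weak peaks fall out by rank. The optimal peaks were the strongest entries of a list called on the pooled reads of the same replicates, so a match above chance was built in and no p-value is given. Against the full replicate lists, 95.6%, 96.5% and 99.1% of the optimal summits were matched in replicates 1, 2 and 3.

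**Figure D1:**
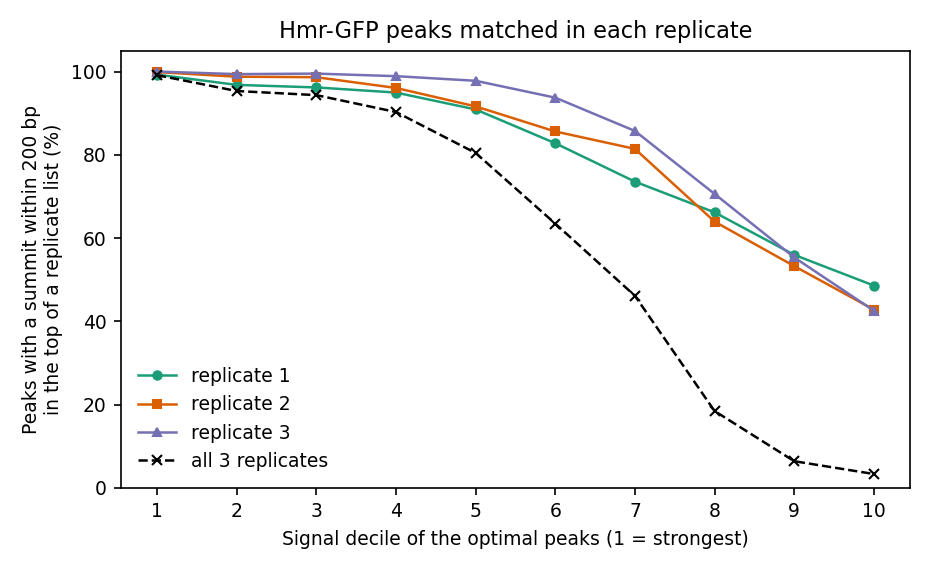
Share of optimal peaks (percent, y axis) with a summit within 200 bp in the top of each replicate list, by decile of the authors' signal (x axis, 1 is the strongest), for each replicate and for all 3 together. The share matched in all 3 fell from 99.1% in the strongest decile to 3.32% in the weakest.

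The order of peak strength was also shared in part. Across peaks matched in both full lists, Spearman's rho was 0.63 between replicates 1 and 2, 0.69 between 1 and 3 and 0.76 between 2 and 3. These correlations run across peaks, which are not independent replicates and were chosen by the pooled signal of the same replicates, so no p-value is given.

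Summits spread almost evenly over the 5 large arms and were sparse on chromosome 4, a small and largely heterochromatic chromosome. Density was 64.8 summits per Mb on 2L, 60.9 on 2R, 59.8 on 3L, 59.8 on 3R and 61.5 on X, but 13.4 on chromosome 4, which had 18 summits. Against the background regions, which were even sparser relative to the arms on chromosome 4 (18 of 20064), the share on chromosome 4 was higher, with an odds ratio of 2.47 and adjusted p = 0.0263 by Fisher's exact test. In the dm3 lists it was 4.91 (adjusted p = 0.000582, same exact test). Against random positions in the assembly this turned round, with an odds ratio of 0.232 and adjusted p = 8.58e-12 by the same exact test. The share on 2R was also slightly above background, with an odds ratio of 1.11 and adjusted p = 0.0191 by Fisher's exact test, and this call was lost without replicate 3 (odds ratio 1.09, adjusted p = 0.0878), with the lower-ranked part of the background (1.09, adjusted p = 0.0643) and against random positions of the 6 chromosomes (1.04, adjusted p = 0.446), by the same exact test. The other 4 chromosomes did not pass the threshold against background.

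The centromere-proximal part of the assembly, which is rich in heterochromatin, held few summits. It made up 8.48% of the length of the 6 chromosomes and held 53 summits, or 0.652% of them (95% interval 0.489% to 0.852%). Background regions lay there as rarely, at 0.738%, and the odds ratio of 0.883 did not differ from 1 (p = 0.482, Fisher's exact test). Against random positions in the assembly the share was lower, with an odds ratio of 0.0408 (p = 1e-300, Fisher's exact test), and against random positions of the 6 chromosomes that the lists cover it was 0.0725 (p = 2.02e-181, same exact test). Random positions were drawn without regard to where reads can be placed, and only 37.2% of the 32-mers in the proximal arms were unique. These odds ratios may therefore overstate the difference. Per Mb of unique 32-mers the proximal arms held 9.40 summits, against 72.1 on the rest of the arms.

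Summits gathered at transcription starts. Promoter summits made up 38.5% of the optimal set (3131 summits, 95% interval 37.4% to 39.6%) and 12.8% of background regions, an odds ratio of 4.27 with p = 1e-300 by Fisher's exact test. The median distance to the nearest start was 577 bp for optimal summits and 2640.5 bp for background. Within 250 bp of a start, 77.0% of optimal summits lay upstream of it, against 57.4% of background regions. The most frequent position was 0 to 100 bp upstream, with 15.9% of all optimal summits, followed by 100 to 200 bp upstream with 10.5%. Introns held 40.4% of optimal summits and 52.5% of background regions, and intergenic sequence held 16.8% and 27.4%. Coding sequence held 30 optimal summits, or 0.369%, against 2.51% of background regions. All 3 of these classes were lower than in background, with adjusted p at or under 9.76e-75 for introns and intergenic sequence and 2.08e-42 for coding sequence by Fisher's exact test. The classes exclude each other and promoters were assigned first, so the higher promoter share lowers the other shares by construction. These p-values are therefore not separate results, and the classes were not compared among non-promoter summits alone.

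**Figure D2:**
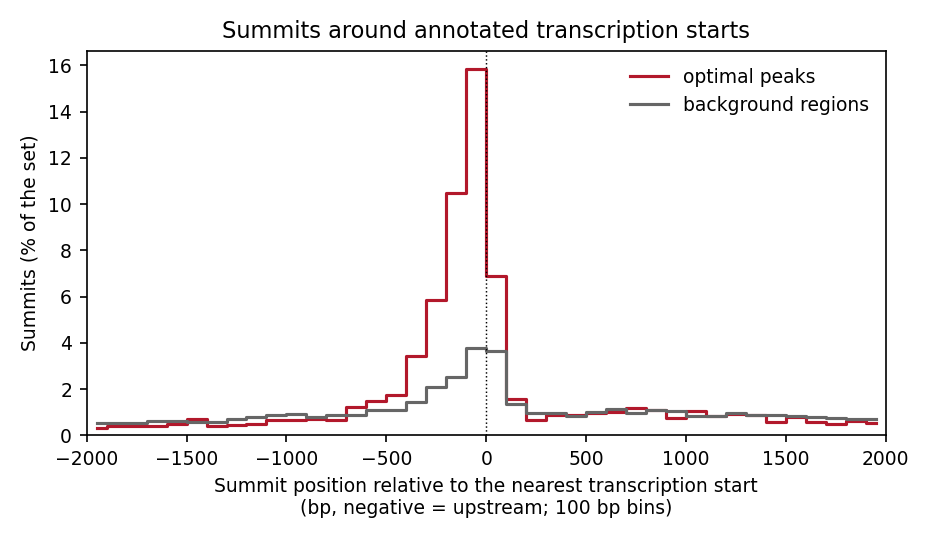
Position of summits relative to the nearest annotated transcription start (x axis, bp in bins of 100 bp, negative is upstream) as percent of the optimal summits or background regions (y axis). Optimal summits peak at 15.9% in the bin just upstream of the start.

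Peaks at promoters were stronger than distal ones. The median signal was 308 (quartiles 213 and 512, n = 3131) at promoters and 243 (quartiles 187 and 369, n = 3416) at distal sites. The difference of 64.6, a ratio of 1.27, had a permutation p of 1e-05, the smallest that the resamples could give. Without replicate 3 the difference was 102 (permutation p = 1e-05). Of the 100 strongest peaks, 67 lay at promoters and 14 at distal sites.

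Genes of the cytoplasmic ribosome had the highest share of all 22 lists, though the lists were not tested against each other. Of the 92 ribosomal protein genes, 76 had a summit at a start (82.6%, 95% interval 73.3% to 89.7%), against 23.0% of other protein-coding genes. The odds ratio was 15.9, with adjusted p = 6.17e-32 by Fisher's exact test. The strongest peaks lay at RpL7 on 2L from 10200846 to 10201228, with a signal of 2885, at RpS27 on 3R from 25247332 to 25247807, with 2463, and at RpL23A on 3L from 1668558 to 1668947, with 2237. Their summits lay 43 bp and 5 bp from the starts of the first 2 genes, in the transcribed part or at its edge, and 74 bp upstream of RpL23A. All 3 peaks were matched in all 3 replicates. The RpL7 peak held the M1BP sequence at 10200989 to 10200997, read on the plus strand as AGTGTGACC.

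Polycomb and trithorax group genes, which encode chromatin regulators, and genes of the mitochondrial ribosome also had summits more often. Of 18 Polycomb and trithorax genes, 11 had a summit (61.1%, odds ratio 5.16, adjusted p = 0.00272, Fisher's exact test), led by brm, a chromatin remodeller, with a signal of 1446, E(z), a histone methyltransferase, with 1232, and Su(z)12 with 445. Without replicate 3, that is with only the optimal peaks matched in both other replicates, this call was lost (odds ratio 3.34, adjusted p = 0.0616, exact test). It was also lost with the peaks of above-median signal (odds ratio 2.79, adjusted p = 0.14, exact test) and with peaks matched in all 3 replicates (odds ratio 3.47, adjusted p = 0.0522, exact test). Each of these settings keeps fewer of the same peaks. Of 73 mitochondrial ribosomal protein genes, 30 had a summit (41.1%, odds ratio 2.30, adjusted p = 0.00272, Fisher's exact test), led by mRpL41 with a signal of 3489, mRpS10 with 3197 and mRpL23 with 2045. The mRpS10 summit lay 133 bp from its start and 124 bp from that of Art3. The mitochondrial call was lost when a summit counted only for its nearest start, which left 17 genes (odds ratio 1.25, adjusted p = 0.721, exact test). The threshold was also missed without replicate 2 (odds ratio 1.94, adjusted p = 0.0508), without replicate 3 (1.98, adjusted p = 0.0616) and with the peaks of above-median signal (1.97, adjusted p = 0.062), by the same exact test.

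Several lists tied to chromatin and cell growth did not differ from other genes past the adjusted threshold of Fisher's exact test. Among Hmr, HP1 and their partners, 9 of 24 genes had a summit (37.5%, odds ratio 1.97), with HP4 at a signal of 713, HP5 at 409 and vig at 359. The HP5 summit lay 244 bp from its start but 156 bp from that of Evi5. Among insulator genes 7 of 19 had a summit, with Chro at 3514, Cp190 at 1621 and Dref at 1145, the last sharing its peak with RpL13, whose start was 18 bp away. The insulator odds ratio of 1.91 rose to 3.06 without replicate 3 and to 3.25 with the peaks of above-median signal. Neither passed (adjusted p = 0.0632 and 0.0646, Fisher's exact test). Proteasome genes had 12 of 32, led by Rpn3 at 624 (odds ratio 1.97, but 1.21 without replicate 3 and 0.946 with nearest starts only). Replication and cell cycle genes had 8 of 23, led by Dp at 1214 (odds ratio 1.75, but 2.80 without replicate 3). Telomere genes had 3 of 7, namely ver at 876, the gene of HP1a at 358 and woc at 249, and their odds ratio of 2.46 turned to 0.748 without replicate 2 and to 0.683 with nearest starts only. The ver summit lay 210 bp from its start but 203 bp from that of Gcn5. The summit at the HP1a gene lay 173 bp from its start but 52 bp from that of Ssb-c31a. Heat shock genes had 5 of 16, with Hsp83 at 2410, Hsp27 at 1841 and Hsp26 at 635, and the Hsp70 copies in this list are uncertain. The piRNA list had 7 of 28, led by papi at 2297, with spn-E at 308 and vas at 279, and its odds ratio of 1.09 turned to 0.667 with the peaks of above-median signal.

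Chemoreceptor genes, which are used in sensory neurons, had few summits. Of 119 chemoreceptor genes, 2 had one (1.68%, odds ratio 0.0554, adjusted p = 1.42e-10, Fisher's exact test), namely Gr21a and Gr63a. The Gr63a summit lay 250 bp from its start but 47 bp from that of Lamtor4. Other small lists did not differ from other genes past the threshold. Segmentation genes had 2 of 20, hry at 364 and wg at 207, neural genes 2 of 15, brat at 370 and pros at 190, and Hox cluster genes 1 of 10, bcd at 486. Muscle genes had 4 of 16, led by Mef2 and Tm1, whose signals were 298 and 297. The testis list had 1 of 18, bol, whose peak lay nearer to Dhpr, and the eggshell list 0 of 14. Dosage compensation genes had 1 of 6, Clamp at 407, and centromere genes 0 of 10. Among these lists the eggshell genes were lower than other genes with starts within 500 bp (adjusted p = 0.047, Fisher's exact test) and within 1000 bp (adjusted p = 0.0272, same exact test). The small lists leave wide intervals, such as 0% to 30.8% for the centromere genes.

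Of the genes of short structured RNAs, those of tRNAs had few summits. Of 295 tRNA genes, 10 had one (3.39%, odds ratio 0.145, adjusted p = 5.13e-15, Fisher's exact test), and the strongest, tRNA:Tyr-GTA-1-8 on 3R with a signal of 2219, lay 204 bp from its summit inside CG8036. The tRNA odds ratio ranged from 0.077 to 0.0947 without 1 of the replicates, with 4 to 5 genes, and was 0.475 with starts within 1000 bp, with 47 genes. None of 111 histone genes had a summit, but 0 of 111 had a mostly unique start, so this 0 cannot be told from reads that were not placed. The snRNA list had 4 of 32, led by snRNA:7SKa at 422 and snRNA:U1:95Ca at 356, and did not pass the threshold of the same exact test.

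**Figure D3:**
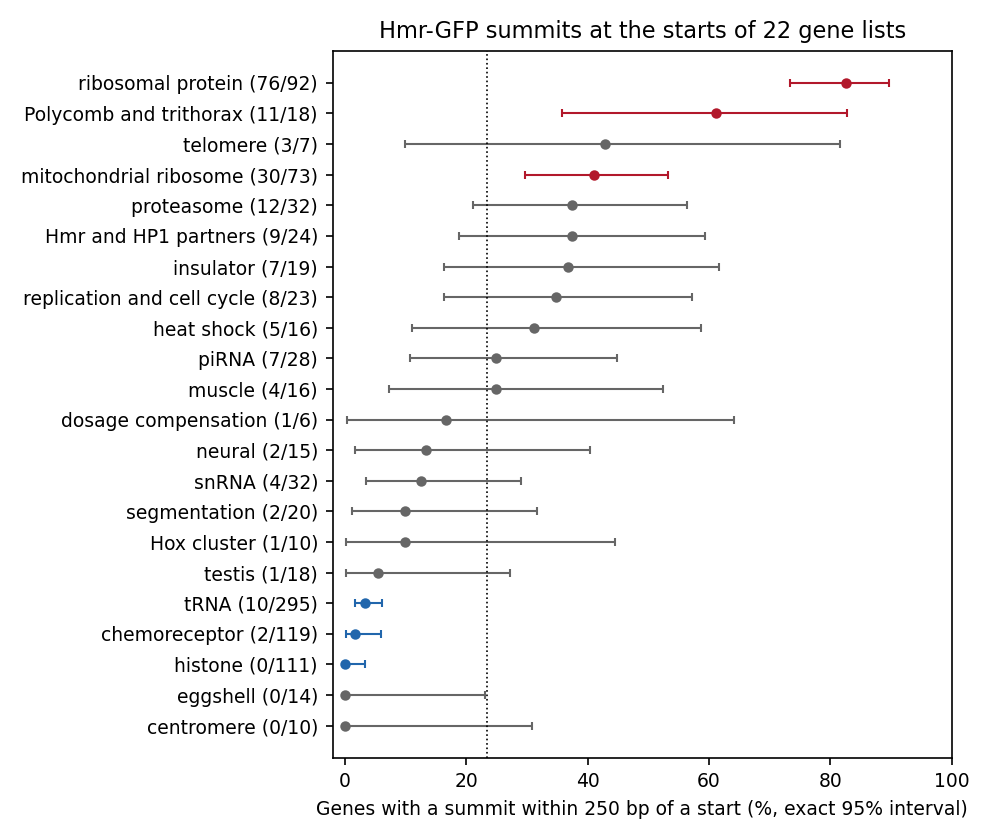
Share of the genes of each list with a summit within 250 bp of a start (percent, x axis), with exact 95% intervals. The counts stand beside each name, the dotted line is the share of all protein-coding genes (23.4%), red marks lists above other genes, blue lists below them and grey lists not past the adjusted threshold; the ribosomal protein genes stand at 82.6%.

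Genes in head-to-head pairs were counted as having a summit more often than others. Of the 3260 protein-coding genes with a summit, 1496 (45.9%, 95% interval 44.2% to 47.6%) had a head-to-head partner, against 2319 of 10685 genes without a summit (21.7%). The odds ratio was 3.06 with p = 8.62e-152 by Fisher's exact test. A summit between 2 starts counts for both genes, so the genes of a pair are not independent. A head-to-head gene can also gain a summit from its partner, so the odds ratio is partly built in. The 1496 genes rested on 928 summits, and no count with nearest starts only was run for this result.

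Of 16 consensus sequences, 10 were more frequent at summits than in flanks, though each of the most enriched ones was found at few summits. The M1BP sequence, bound by a pausing factor at housekeeping promoters, was found within 100 bp of 2.61% of summits and in 0.271% of flanks, a ratio of 9.64. The DRE, TATCGATA, the site of the replication-related factor Dref, was found at 3.37% against 0.621%, a ratio of 5.43. The CTCF sequence had a ratio of 4.35, Su(Hw) 2.94, Ohler 7 a ratio of 1.94, Ohler 6 a ratio of 1.83, the TATA box 1.52, the BEAF-32 core 1.32, GATA 1.21 and Caudal 1.08. All 10 had adjusted p at or under 0.0325 by the exact McNemar test, and the E-box was lower, with a ratio of 0.787 (adjusted p = 0.00927, same exact test). The calls of GATA, Caudal and the E-box were each lost without at least 1 of the replicates and with the peaks of above-median signal (adjusted p from 0.0797 to 0.348, same exact test). Against background regions in place of flanks the ratio of CTCF was 2.16 and that of Su(Hw) 1.29. Su(Hw), GATA and Caudal did not pass against background regions in place of flanks (adjusted p from 0.0558 to 0.708, Fisher's exact test).

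The sequences were also counted apart at promoter peaks and at other peaks. At promoter peaks the ratio was 17.0 for M1BP, 8.55 for the DRE, 3.33 for Ohler 7 and 1.86 for the BEAF-32 core, each with adjusted p at or under 4.76e-45 by the exact McNemar test. At other peaks the same 4 sequences had ratios of 1.52, 1.21, 1.01 and 0.982, and none passed the exact test. The CTCF sequence was enriched in both classes, with ratios of 4.14 at promoters and 4.49 elsewhere (adjusted p = 3.18e-07 and 1.58e-11, exact McNemar test). The GAGA factor sequence moved in opposite directions, with ratios of 1.45 at promoters and 0.776 elsewhere (adjusted p = 0.0232 and 0.0326, exact McNemar test). The initiator did not pass over all peaks (ratio 1.06) but was higher at promoters, with a ratio of 1.29 (adjusted p = 2.57e-07, same exact test). Elsewhere its ratio was 0.934 and did not pass. The difference between the classes was not itself tested. Named peaks with a DRE included Prosalpha5 on 2R at 17412747 to 17412754, Rpn3, spn-E and brat.

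**Figure D4:**
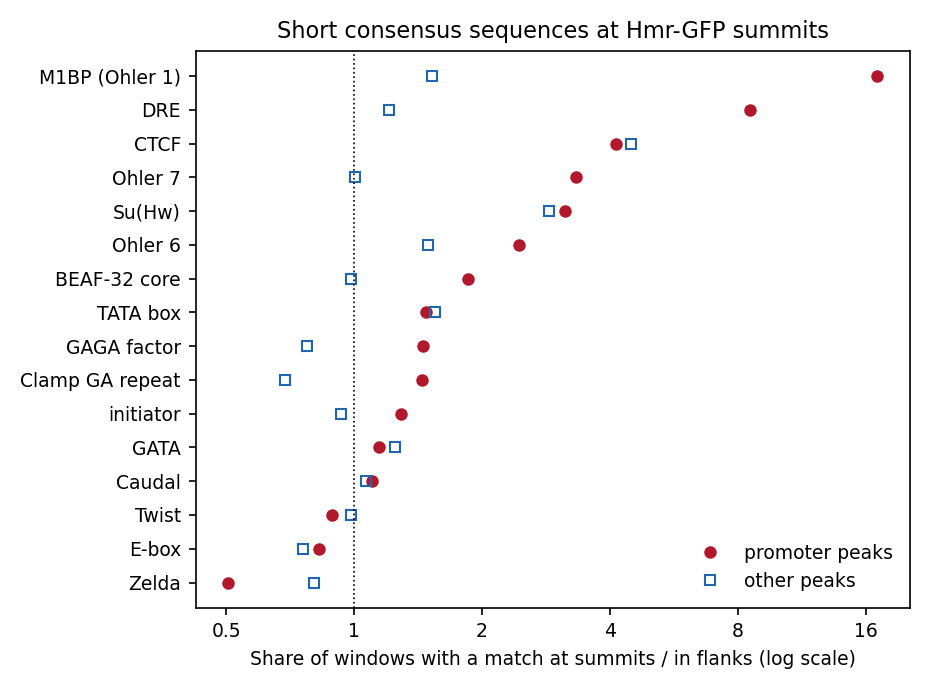
Ratio of the share of windows with a match at summits to that in flanks (x axis, log scale) for 16 consensus sequences, at promoter peaks (filled circles) and at other peaks (open squares). M1BP and DRE reach 17.0 and 8.55 at promoters and lie at 1.52 and 1.21 elsewhere.

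Summit windows held slightly more soft-masked sequence than background regions. The mean share was 19.8% against 17.1%, a difference of 2.74 percentage points with a permutation p of 1e-05, the smallest that the resamples could give. The direction turned against random positions in the assembly, where the difference was -2.86 percentage points (permutation p = 1e-05). Against random positions of the 6 chromosomes that the lists cover it was -0.244 (permutation p = 0.388). Annotated transposable elements held 0.184% of summits and 0.344% of background regions, and the kind of masked sequence at summits was not examined.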

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

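The tests of tRNA genes with unique starts, and those of unique starts at ribosomal protein genes and on chromosome 4, were chosen only after the result was seen.

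The dm3 lists hold entries on sequence named as heterochromatic or unplaced. These entries came in only with the dm3 alternatives and were not set against genes or consensus sequences, which is why they are named here. In dm3, 7 optimal peaks lay on heterochromatic or unplaced sequence, 4 on 2RHet, 2 on 3RHet and 1 on U. The strongest, on 2RHet from 370000 to 370267 in dm3, had a signal of 761, rank 771 of 7522, and was matched in all 3 replicates. The pooled relaxed list of dm3 held 69 entries on such sequence.

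Summits on chromosome 4 and near centromeres were fewer than on the rest of the arms. This was not only a matter of starts at which reads can be placed. Among protein-coding genes with mostly unique starts, 3.75% of 80 genes on chromosome 4 had a summit (95% interval 0.78% to 10.6%), against 24.2% elsewhere. In the proximal 2 Mb of the arms it was 12.3% of 106 genes (95% interval 6.69% to 20.1%), against 24.3% on the rest of the arms. A removal of whole 100 kb bins of chromosome 4 from the lists is argued against, since 0 of its 13 bins held no relaxed entry. A single entry in the pooled list or any replicate list was enough, and the sparsest bin held 2. A removal of shorter stretches is therefore not excluded. A control rich in heterochromatic reads and fewer open promoters there stay open, and no biological explanation was tested because the design has 1 group.

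Ribosomal protein genes had the highest share of summits among the gene lists. Signal at any strongly transcribed gene would also mark tRNA genes, but 3.70% of the 270 with mostly unique starts had a summit (95% interval 1.79% to 6.71%), against 20.3% of other genes. Summits of head-to-head neighbours do not account for the pattern, since the odds ratio was 17.8 (95% interval 9.22 to 37.1) among genes without such a partner. Better placement of reads does not either, with an odds ratio of 15.3 (95% interval 8.84 to 28.2) among genes with mostly unique starts. Recovery of any open, strongly transcribed polymerase II promoter stays open, as no expression values and no control without the tag were analysed here, and no biological explanation was tested.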

How the results depend on the processing

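The alternatives with mostly unique starts, the gene of the nearest start, random positions of the 6 chromosomes and the strongest summit within 500 bp were chosen only after the data were seen. Apart from agreement and rank correlation, without a replicate again means the optimal peaks matched in the top lists of both other replicates. These are fewer peaks of the same pooled calls.

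Promoter share, the signal difference between promoter and distal peaks and the head-to-head share kept their direction and their side of the threshold under every alternative run. Mean agreement ranged from 77.9% (match within 100 bp) to 97.2% (peaks of above-median signal), the promoter odds ratio from 3.47 to 7.91 and the head-to-head odds ratio was at least 2.58. The choice of background decided the results on heterochromatin and repeats. With random positions of the assembly the chromosome 4 odds ratio was 0.232, the proximal one 0.0408, the repeat difference -2.86 percentage points, the odds ratios of 2L and 3L 1.16 and 1.08, and 5 chromosomes passed the threshold. With random positions of the 6 chromosomes these were 0.201, 0.0725 and -0.244 percentage points (permutation p = 0.388), and 1 chromosome passed. With the lower-ranked part of the background, 1 chromosome passed in place of 2, and without a replicate it was 1 to 4. The number of gene lists above other genes, 3, was 1 with the peaks of above-median signal and 1 to 3 without a replicate, and the number below, 3, was 4 with starts within 500 bp and within 1000 bp, where the eggshell list was added, and 2 with mostly unique starts and with genes that have a pooled entry within 1000 bp, where no histone gene was left to test. The ribosomal list was past the threshold in every setting. The number of sequences above flanks, 10, was 5 at non-promoter peaks. The number below, 1, was 2 with 50 bp windows, 2 at non-promoter peaks, 0 at promoter peaks, 3 for peaks in the top of all 3 replicates and 2 to 3 without a replicate. The BEAF-32 core fell to 0.982 at non-promoter peaks, Caudal was 0.985 against background regions, and the GAGA factor sequence, 0.987 in the main comparison, was 1.23 against background regions and 1.45 at promoter peaks but lower, past the threshold, with 50 bp windows (0.695), at non-promoter peaks (0.776), with the peaks of above-median signal (0.769), for peaks in the top of all 3 replicates (0.728) and without replicates 1 and 3 (0.746 and 0.737). Zelda, 0.653 in the main comparison and not past the threshold, was lower past it without each replicate (0.592 to 0.605) and for peaks in the top of all 3 replicates (0.590). The chromosome 4 odds ratio was 4.91 with the dm3 lists. GATA was also lost with 50 bp windows and for peaks in the top of all 3 replicates. Except where the construction shows it, the cause was not tested. Over single gene lists 209 of 218 comparisons were the same, and over single sequences 122 of 160. A comparison also counted as the same when neither run passed the threshold, even where the direction turned. Lists and sequences that did not pass in the main comparison therefore raise these counts, which do not measure how firm the calls are. Among gene lists 7 comparisons were weaker and 2 stronger, and among sequences 22 were weaker, 12 stronger and 4 reversed. No paired analysis was possible because there is 1 group. Without depths, differences of signal between replicates could not be judged.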

Other observations

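The comparisons of sequences between classes of promoter peaks and of genes, the counts in transposable elements and the test of letter orders for the TATA box were chosen only after the result was seen, and the tests of DRE and M1BP were written before.

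Several sequences differed between ribosomal protein promoters and other promoter summits. The DRE lay within 100 bp of 27.6% of the 76 summits at ribosomal protein genes, against 7.43% of the other 3055 promoter summits (odds ratio 4.76, adjusted p = 2.89e-06, Fisher's exact test). The BEAF-32 core, which the DRE contains, was found at 67.1% against 40% (odds ratio 3.06, adjusted p = 2.2e-05, Fisher's exact test). The E-box, less frequent at summits in general, was found at 10.5% of them against 2.19% (odds ratio 5.25, adjusted p = 0.00202), and Ohler 6 at 22.4% against 10.1% (odds ratio 2.57, adjusted p = 0.00561), by the same exact test. The initiator (6.58% against 20.9%) and the TATA box (15.8% against 29.7%) were rarer, with adjusted p of 0.00527 and 0.0193 by Fisher's exact test, and the GAGA factor sequence was found at 0 of 76 against 5.86% (adjusted p = 0.0481, same exact test). M1BP, at 11.8% against 6.12%, did not pass (adjusted p = 0.0868, Fisher's exact test).

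Summits at head-to-head starts also differed from other promoter summits. Of 928 such summits, 27.0% held Ohler 7 against 17.4% of the other 2203 (adjusted p = 1.47e-08, Fisher's exact test), and 10.3% held the DRE against 6.90% (adjusted p = 0.00372, same exact test). The TATA box was also more frequent, at 36.6% against 26.2% (odds ratio 1.63, adjusted p = 4.25e-08, Fisher's exact test). The GAGA factor sequence was rarer, at 1.62% against 7.44% (odds ratio 0.204, adjusted p = 2.52e-11, Fisher's exact test). Sequences were also counted within 250 bp of the most upstream start of each protein-coding gene. The summit of a gene may lie at another of its starts, and these wider windows are not comparable with the summit windows. M1BP was found at 11.0% of 3260 genes with a summit and 5.15% of 10685 genes without one (odds ratio 2.28, adjusted p = 2.53e-28, Fisher's exact test). Ohler 7 was also more frequent at genes with a summit (36.2% against 21.8%, adjusted p = 2.25e-57, same exact test). So was the GAGA factor sequence (9.60% against 7.08%, adjusted p = 7.2e-06, same exact test). At genes with a summit the initiator was rarer (40.6% against 48.8%, adjusted p = 7.72e-16, Fisher's exact test). The TATA box (52.9% against 55.6%, adjusted p = 0.00885), GATA (12.2% against 15.2%, adjusted p = 4.55e-05) and Caudal (25.5% against 27.5%, adjusted p = 0.0247) were rarer there too, by the same exact test.

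The strength of promoter peaks differed with some of these sequences, but no difference passed the threshold for the DRE or M1BP. The hypothesis that a DRE goes with a stronger peak could not be decided. The median signal with a DRE was 0.989 times that without (permutation p = 0.817), and no interval was computed for this ratio. For M1BP the ratio was 0.977 (permutation p = 0.657), which leaves the same hypothesis undecided there. Median signal was higher with the TATA box (345 against 300, adjusted permutation p = 0.0016) and with Ohler 7 (330 against 304, adjusted permutation p = 0.0244). Before adjustment the permutation p of the TATA box was 0.0001, the smallest that the 10000 resamples could give. It was lower with the GAGA factor sequence (243 against 313, adjusted permutation p = 0.00693) and with the initiator (281 against 318, adjusted permutation p = 0.004). The hypothesis that DRE and M1BP lie in separate promoter peaks could not be decided, with 19 peaks holding both and an odds ratio of 1.27 (95% interval 0.732 to 2.09, Fisher's exact test p = 0.338). None of the 15 strongest peaks held a DRE, M1BP, CTCF or Su(Hw) sequence within 100 bp of the summit. Over all optimal peaks the shares were only 3.37%, 2.61%, 1.98% and 0.959%, so 15 peaks are too few to read this as a trait of strong peaks.

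Base composition may account for part of the sequence results. Summit windows were 62.4% A or T, against 57.3% in flanks. When the letters of each consensus were put in other orders, 0% of the orders had as high a ratio for the DRE, M1BP, CTCF, Ohler 6 and Ohler 7, and 2.5% for Su(Hw), so composition alone is argued against for these 6. For the TATA box 50% of 14 orders, for GATA 36% of 200 orders and for Caudal 91.5% of 200 orders reached as high a ratio. The richness of summits in A and T could account for these. For the BEAF-32 core 6.78% of 59 orders reached as high a ratio. The median ratio of its orders was only 1.05, against 1.32 for the core, so composition was not decided for it.

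Few summits lay in annotated transposable elements, 15 of 8131 (0.184%) against 0.344% of background regions (odds ratio 0.536, p = 0.0292, Fisher's exact test). Of these, 8 lay in INE-1 elements, but this was not set against the abundance of the family, so no preference can be read from it. Whether reads could be placed in these elements was not examined, and promoter summits were not set aside. Among the 2000 strongest entries of each replicate, 0 in replicate 1, 17 in replicate 2 and 18 in replicate 3 had no entry within 500 bp in either of the other full lists.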
